A study of Mus musculus and Homo sapiens with 14 samples.

How the data were processed

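Gene expression was measured by sequencing of poly(A)-selected RNA with a directional library kit, over 75 cycles on a NextSeq500, in 14 libraries from 3 cell lines. Per the labels, the cells grew with 20 ng/mL of EGF and of bFGF, and each culture condition had 2 biological replicates. The deposited values are TPM, transcript abundances scaled to a total of 1000000 per library and summed per gene, in 1 table for each line, with 1 column for each library. The authors' processing notes name FastQC 0.11.8, MultiQC 1.7, Salmon 0.14.1 and DESeq2 1.22.2, with the genome builds GRCm38 and GRCh38. Each column was checked to sum to 1000000. The tables hold no counts, so the sequencing depth of each library is unknown, no test on counts was run and no counting interval is given.

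The 2 mouse tables list 35288 gene identifiers each and the human table lists 37788. Symbols, gene classes and positions of mouse genes came from the GENCODE M21 annotation of GRCm38. The files used here do not pair the human identifiers with gene names. For D341, gene list tests, the overlap with the MB1 response, the check of marker genes and the rescaling without mitochondrially encoded genes were therefore not run.

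Genes with at least 1 TPM in at least 2 libraries of a table were tested, 12280 in Oli-neu, 12407 in MB1 and 12403 in D341. Values were analysed as log2(TPM + 1) with limma 3.58.1 in R 4.3.3, with a mean-variance trend in the empirical Bayes step. The tests were two-sided, and p values were adjusted by the Benjamini-Hochberg method over the genes tested in each comparison, with a threshold of 0.05. The 6 Oli-neu libraries shared 1 fit, from which 3 comparisons were drawn, and MB1 and D341 were fitted apart, each with 4 libraries. Reported errors are the SD of the 2 libraries of a group for TPM, and the moderated standard error (SE) for a log2 fold change.

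Mouse genes were also grouped in 34 lists of pathways, complexes and cell type markers. The lists, the groups, the comparisons, the tests and the rule for naming genes were fixed before the data were examined. A list with at least 5 tested members was compared with all other genes by limma's camera function with a preset correlation between genes of 0.01, and p values were adjusted over the lists of a comparison. Beside it, camera with an estimated correlation was run, and limma's fry function, which tests a list against no change and not against other genes. Within each list, the p values of its members were also adjusted over the list alone.

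Genes were named by rule. Where at least 5 genes passed the threshold, with the libraries of 1 group all above or all below those of the other and a mean of at least 5 TPM in 1 group, up to 12 with the highest and 12 with the lowest fold change were taken. Where fewer passed, the 10 with the smallest p were taken and are said not to pass. Up to 4 members with the smallest p were added for each list past the threshold and for the list of extracellular vesicle genes. Predicted and unnamed gene models, pseudogenes and mitochondrial genes were left out of the first part of the rule. For D341, whose identifiers have no names here, at most 2 identifiers are printed in each direction. List members that passed when adjusted over the list alone are also named, and those outside the rule were chosen after their values were seen.

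Alternatives were pseudocounts of 0.1 and 5 TPM, no filter and a filter of 5 TPM, median-ratio scaling of the columns, rescaling without mitochondrially encoded genes, limma without a trend and with robust=TRUE, a minimum absolute log2 fold change of 1, the replicate number as a covariate, a fit of the 4 libraries compared, and each library left out in turn. Where 1 library of a group was left out, the remaining one was assumed to vary like the other groups. A test of protein-coding genes alone, with TPM rescaled over them, and list tests on the 4 libraries compared were chosen after seeing the data. The overlap of the Oli-neu responses was set against 100 simulations of unchanged groups that shared the same monoculture libraries, and the simulation of the counts of genes at an unadjusted p under 0.05 was chosen after seeing the data. Transcripts of the partner line were followed with genes at 50 TPM or more in the partner and under 0.1 TPM in the host grown alone.

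The procedure was tested on simulated data with the mean and spread of each gene and independent noise, so that correlation between genes was not simulated, 20 times for each comparison with 200 changed genes. It recovered 32.8% to 57.7% of genes changed 2-fold and 88.7% to 98.3% of genes changed 4-fold, with a mean of 7.15 to 15.6 false calls. The simulated spread of a gene was its moderated spread, which differs less between genes than the measured one. With 200 changed genes the adjusted threshold is also easier to reach than where fewer change. These shares thus need not hold for the measured data. A list shifted by -0.5 was found in 20 of 20 simulations in each mouse comparison.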

Results

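Gene expression was profiled in 3 cell lines grown alone or beside another line. Oli-neu is a mouse line of oligodendrocyte precursor cells, the cells that give rise to myelinating oligodendrocytes. MB1 was derived from a Sonic hedgehog medulloblastoma of a mouse at postnatal day 12, and D341 is a human Group 3 medulloblastoma line. In co-culture the lines shared medium across an insert of 30 mm with pores of 0.4 µm. The 14 libraries formed 7 groups of 2: Oli-neu alone, with MB1 and with D341, MB1 alone and with Oli-neu, and D341 alone and with Oli-neu. Expression is given as TPM, 1000000 in each library, and between 11596 and 12478 genes reached 1 TPM. The depth of the libraries is unknown. Libraries of the same group correlated across genes with r between 0.953 and 0.979, where genes are not independent replicates. Among the Oli-neu libraries, the first principal component held 53.6% of the variance and separated the libraries numbered 1 from those numbered 2 in all 3 groups.

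Lineage genes were measured in the mouse lines. Oli-neu alone expressed the oligodendrocyte lineage factor Sox10 at 184 ± 18.0 TPM (SD, n = 2), Olig2 at 70.4 ± 7.99 TPM, the precursor receptor Pdgfra at 12.6 ± 0.841 TPM and myelin basic protein, Mbp, at 72.3 ± 5.54 TPM. MB1 alone expressed Zic1, a factor of cerebellar granule neuron precursors, at 74.0 ± 14.6 TPM, the hedgehog receptor Ptch1 at 16.3 ± 2.96 TPM and Olig2 at 237 ± 13.2 TPM (SD, n = 2), while Sox10 was at 0.674 ± 0.294 TPM. The hedgehog effector Gli1 was at 0.154 ± 0.0344 TPM in MB1 alone, and Atoh1 was at 0 and 0.0143 TPM in its 2 libraries. Genes annotated as pseudogenes were assigned 36.0% to 38.2% of TPM in Oli-neu and 25.2% to 26.8% in MB1. How reads were split between pseudogenes and genes of similar sequence is unknown here, so the TPM of such genes is uncertain. Mitochondrially encoded genes held 1.93% to 4.53% in Oli-neu and 5.73% to 9.56% in MB1.

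Oli-neu cells beside MB1 were compared with Oli-neu cells alone, to see which genes of the precursor line differ when it shares medium with the tumour line. Genes of DNA replication were lower in co-culture. All 30 measured members had a lower mean, with a median log2 fold change of -0.50 against -0.06 for all genes tested (camera adjusted p = 4.68e-17, adjusted p = 0.180 with an estimated correlation). Adjusted over the list alone, 13 members fell and 0 rose, while 0 passed over all genes tested. Thymidylate synthase, Tyms, which makes the precursor of dTTP, fell from 12.7 ± 0.372 to 6.29 ± 0.588 TPM (SD, n = 2), a log2 fold change of -0.91 with an SE of 0.10. The flap endonuclease Fen1 fell from 9.52 ± 0.773 to 5.81 ± 0.201 TPM and the replicative helicase subunit Mcm3 from 39.7 ± 4.75 to 26.9 ± 0.0777 TPM. In 26 of the 30, both co-culture libraries lay below both monoculture libraries. Chance would give 1 in 6 if the libraries were interchangeable, but the Oli-neu libraries separated by number. Members of a list are also not independent of each other, so the 26 are not weighed against that share. The list median was -0.42 between the libraries numbered 1 and -0.53 between those numbered 2.

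Immediate targets of growth factor and ERK signalling were higher beside MB1, in 20 of 24 members, with a median of 0.14 (camera adjusted p = 2.05e-07, adjusted p = 0.180 with an estimated correlation). Adjusted over the list alone 1 member rose, the transcription factor Fos, from 38.8 ± 3.62 to 76.9 ± 5.30 TPM (SD, n = 2). The list's medians within numbers 1 and 2 were 0.12 and 0.08. All 13 mitochondrially encoded genes had a higher mean, with a median of 0.52 (camera adjusted p = 7.85e-08, adjusted p = 0.697 with an estimated correlation), 0.90 within number 1 and 0.25 within number 2. The cytochrome oxidase subunit mt-Co3 was at 1791 ± 279 TPM alone and 3005 ± 153 TPM with MB1 (SD, n = 2), and 0 members passed when adjusted over the list alone. Targets of MYC and genes of ribosome biogenesis were lower in 27 of 29 members, with a median of -0.21 (camera adjusted p = 8.84e-05, adjusted p = 0.180 with an estimated correlation), -0.24 within number 1 and -0.18 within number 2.

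The other 5 lists past the threshold in this comparison had an adjusted p = 0.720 with an estimated correlation. Mitosis genes had a median of -0.32 (camera adjusted p = 5.41e-06), -0.12 within number 1 and -0.50 within number 2. Genes of cholesterol synthesis had a median of -0.25 (0.00283), -0.01 within number 1 and -0.52 within number 2. Genes of lysosomes and autophagy had a median of 0.12 (0.000102), 0.15 and 0.05 within the numbers. The median was 0.09 for TGF-beta and matrix genes (0.00923), 0.17 and 0.01 within the numbers. Astrocyte markers had a median of 0.12 (0.0200), -0.04 within number 1 and 0.28 within number 2, and 1 member rose when adjusted over the list alone, angiotensinogen, Agt, from 7.70 ± 1.94 to 14.9 ± 0.0149 TPM (SD, n = 2). Without Oli-neu alone replicate 2 the lysosome (adjusted p = 0.0574), cholesterol (0.184), matrix (0.114) and astrocyte (0.723) lists no longer passed. Without Oli-neu with MB1 replicate 2 mitosis (0.287), cholesterol (0.446) and astrocyte (0.261) did not pass, nor did the matrix list without replicate 1 (0.251). Without Oli-neu with MB1 replicate 1 the medians were -0.52 for mitosis, -0.42 for cholesterol, 0.02 for lysosome and 0.01 for matrix genes. Without its replicate 2 they were -0.05, -0.11, 0.21 and 0.16, with 0.05 for astrocyte markers. Without Oli-neu alone replicate 2 they were -0.15 for cholesterol, 0.03 for lysosome, 0.05 for astrocyte and 0.99 for mitochondrially encoded genes. Without its replicate 1 the astrocyte median was 0.24. With median-ratio scaling the medians were 0.18 for lysosome, 0.16 for matrix and 0.19 for astrocyte genes. Genes of extracellular vesicle formation and cargo, the subject of the study's title, had a median of 0.01 over 42 members (adjusted p = 0.159) with 0 members passing when adjusted over the list alone.

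Over all genes, limma called 0 genes between Oli-neu with MB1 and alone. At an unadjusted p under 0.05 there were 747, against 614 expected if no gene differed, 176 higher and 571 lower. With the columns scaled by median ratios these were 357 and 351, and 2 genes were called. Dhrs3, which reduces all-trans-retinal to retinol, had the smallest adjusted p and did not pass (adjusted p = 0.0631). It lies on chromosome 4 from 144892827 to 144928209 of GRCm38 and was at 1.85 ± 0.00274 TPM alone and 10.5 ± 0.750 TPM with MB1 (SD, n = 2), a log2 fold change of 2.01 with an SE of 0.11, and passed with a pseudocount of 0.1 TPM (adjusted p = 0.0309) and with median-ratio scaling (adjusted p = 0.0425). Among the other 9 genes with the smallest p, the adhesion molecule neurofascin, Nfasc, was at 0.957 ± 0.155 TPM alone and 8.50 ± 3.47 TPM with MB1, and rose when adjusted over its list of adhesion genes alone. Hes5, a target of Notch signalling, fell from 17.8 ± 0.525 to 10.4 ± 0.256 TPM when adjusted over the Notch list alone. The ligand Wnt4 was at 4.58 ± 0.116 and 8.23 ± 0.668 TPM, the collagen gene Col18a1 at 3.02 ± 0.205 and 6.93 ± 1.13 TPM, Kazn at 8.74 ± 1.04 and 4.40 ± 0.200 TPM, Zswim9 at 9.50 ± 1.02 and 2.09 ± 0.307 TPM, and Rtl3 at 11.5 ± 0.893 and 4.99 ± 0.531 TPM. When protein-coding genes alone were tested, an alternative chosen after seeing the data, Dhrs3 (adjusted p = 0.0104) and Gm10985 (adjusted p = 0.00822) passed. Called counts under the remaining alternatives were 3 with a pseudocount of 0.1 TPM, 1 without a filter and 1 without a trend.

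**Figure D1:**
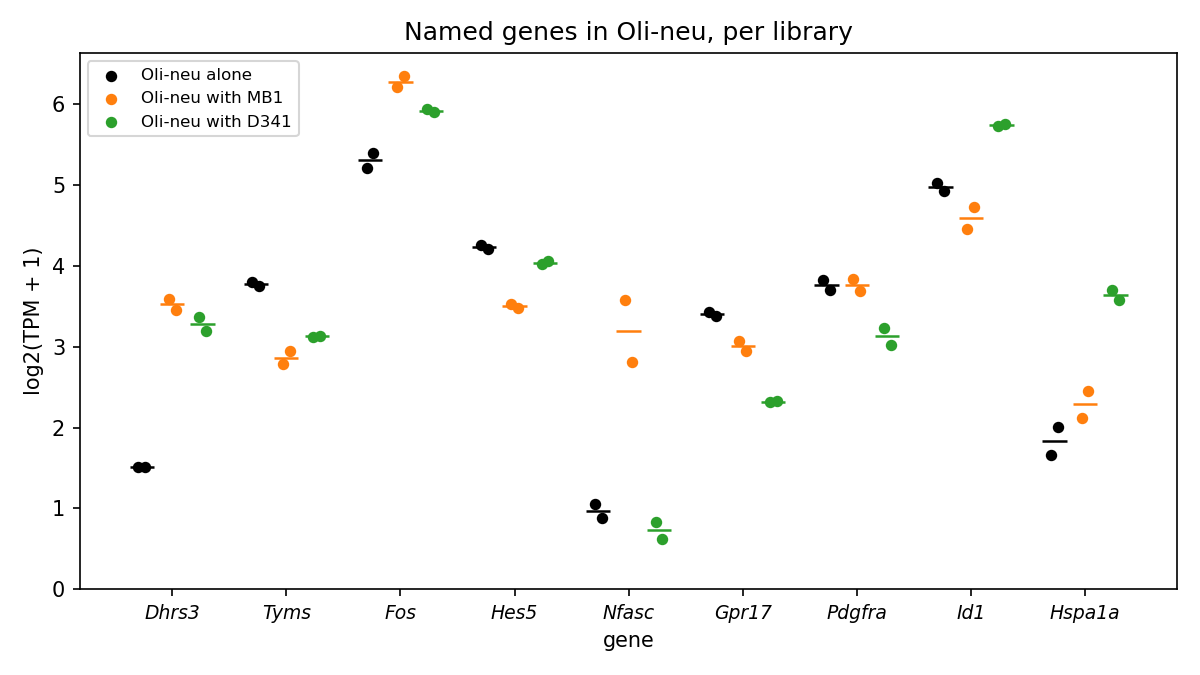
Expression of 9 genes in each Oli-neu library, as log2(TPM + 1), for cells alone, with MB1 and with D341, where points are libraries and bars are means of 2. Dhrs3 was higher in both co-cultures, Nfasc was high with MB1 and Id1 and Hspa1a were high with D341.

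The same Oli-neu alone libraries served for the comparison with the human line D341, which is thus not an independent repeat. Beside D341, DNA replication genes of Oli-neu were also lower than in Oli-neu alone, in 30 of 30 members. The median was -0.40 against -0.16 for all genes tested (camera adjusted p = 5.09e-05, adjusted p = 0.536 with an estimated correlation), -0.34 within number 1 and -0.43 within number 2. Adjusted over the list alone 4 members fell: Tyms to 7.75 ± 0.0495 TPM (SD, n = 2; log2 fold change -0.65, SE 0.10), Uhrf1, which carries DNA methylation through replication, from 14.9 ± 0.487 to 9.77 ± 0.00245 TPM, Mcm6 to 11.1 ± 0.298 TPM and Fen1 to 6.11 ± 0.172 TPM. Targets of BMP signalling had a median of 0.20 (camera adjusted p = 0.000107, adjusted p = 0.536 with an estimated correlation), 0.20 within each number. The inhibitors of differentiation Id1 and Id4 rose when adjusted over the list alone, Id1 from 30.5 ± 1.62 to 52.6 ± 0.421 TPM and Id4 from 6.92 ± 1.02 to 10.4 ± 0.0478 TPM (SD, n = 2).

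Heat shock genes were mixed. Their median was -0.11, while their mean was 0.22 and the test gave a higher direction (camera adjusted p = 0.0274, adjusted p = 0.536 with an estimated correlation), with medians of -0.12 and -0.10 within the numbers. The inducible chaperones Hspa1a, Hspa1b and Hsph1 rose when adjusted over the list alone, Hspa1a from 2.59 ± 0.622 to 11.5 ± 0.729 TPM, Hspa1b from 5.46 ± 1.81 to 21.4 ± 0.872 TPM and Hsph1 from 21.2 ± 0.567 to 33.9 ± 4.16 TPM (SD, n = 2). Hspa1a and Hspa1b are near-identical in sequence, so the split of reads between them is uncertain. Oligodendrocyte precursor markers did not pass as a list, with a median of -0.31 against -0.16 for all genes tested (camera adjusted p = 0.109). For these markers fry, which tests against no change and not against other genes, gave an adjusted p of 0.0111. Of these markers, the receptor Gpr17, which marks precursors committed to differentiate, fell from 9.62 ± 0.273 TPM to 3.97 and 4.03 TPM in the 2 libraries, and Pdgfra fell from 12.6 ± 0.841 to 7.77 ± 0.912 TPM when adjusted over the list alone (SD, n = 2).

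Another 7 lists passed the threshold with D341. Mitochondrially encoded genes had a median of 0.47 (camera adjusted p = 6.76e-09, adjusted p = 0.536 with an estimated correlation), 1.01 within number 1 and 0.11 within number 2. Targets of MYC had a median of -0.28 (0.0120, adjusted p = 0.536 with an estimated correlation), -0.29 and -0.28 within the numbers. Ribosomal protein genes (median 0.04, camera adjusted p = 0.000107), TGF-beta and matrix genes (0.04, 0.00130), ER chaperones (-0.00, 0.00866) and astrocyte markers (0.04, 0.0455) each had an adjusted p = 0.557 with an estimated correlation. Their medians within numbers 1 and 2 were 0.02 and 0.05, 0.03 and 0.05, -0.02 and 0.09, and -0.16 and 0.03. The mean of the ER chaperones was 0.02 and their test gave a higher direction, and Agt, at 13.9 ± 0.720 TPM, rose when adjusted over the astrocyte list alone. Lysosome genes had a median of -0.03 and a mean of -0.01, while the test gave a higher direction (camera adjusted p = 0.0202, adjusted p = 0.589 with an estimated correlation), and -0.11 and 0.05 within the numbers. Without Oli-neu alone replicate 2 the lysosome (adjusted p = 0.231), ER chaperone (0.0694), heat shock (0.182), ribosomal (0.231) and astrocyte (0.518) lists did not pass. Without Oli-neu with D341 replicate 2 the lysosome (0.204), MYC (0.0600), ER chaperone (0.560), heat shock (0.0695) and astrocyte (0.143) lists did not, and without replicate 1 heat shock (0.0540) and astrocyte (0.0629) did not. Median-ratio scaling also ended the heat shock (0.0746) and astrocyte (0.0856) calls. With it the median of all genes tested was 0.00. List medians were then 0.07 for heat shock, 0.15 for lysosome, 0.18 for ER chaperone, 0.23 for ribosomal, 0.17 for matrix and 0.23 for astrocyte genes. They were -0.10 for MYC targets, -0.24 for DNA replication and 0.34 for BMP targets. The BMP median was 0.31 with a pseudocount of 0.1 TPM, and the matrix median 0.08 in a fit of the 4 libraries. With protein-coding genes alone the medians were -0.00 for lysosome, 0.03 for ER chaperone, 0.03 for matrix, 0.07 for ribosomal and 0.07 for astrocyte genes. The BMP median was 0.10 without Oli-neu with D341 replicate 1. That of mitochondrially encoded genes was 0.99 without Oli-neu alone replicate 2 and 0.71 without Oli-neu with D341 replicate 2. With each of the 4 libraries left out in turn the medians ranged from -0.22 to -0.01 for heat shock, -0.09 to 0.19 for ribosomal, -0.01 to 0.11 for matrix, -0.04 to 0.10 for ER chaperone, -0.05 to 0.03 for lysosome and -0.03 to 0.13 for astrocyte genes. Mitosis genes did not pass, with a median of -0.28 and 28 of 30 members lower (camera adjusted p = 0.0795). Extracellular vesicle genes had a median of -0.11 (adjusted p = 0.418) with 0 members passing when adjusted over the list alone.

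Over all genes limma called 0 genes with D341 against alone. At an unadjusted p under 0.05 there were 1684, against 614 expected if no gene differed, 198 higher and 1486 lower. With median-ratio scaling these were 608 and 445, with 0 called. Dhrs3 was at 8.74 ± 0.803 TPM (SD, n = 2; log2 fold change 1.77, SE 0.11) and did not pass (adjusted p = 0.198). The receptor tyrosine kinase gene Kit was at 22.3 ± 0.806 TPM alone and 11.8 ± 0.0827 TPM with D341, the complement gene C4b at 39.5 ± 3.13 and 83.4 ± 8.74 TPM, and Zfp865 at 4.42 ± 0.0459 and 9.13 ± 0.369 TPM. Lower values with D341 were measured for Zfp397, 3.88 ± 0.181 TPM from 8.38 ± 0.614, Slc35a5, 3.61 ± 0.345 TPM from 9.91 ± 1.51, Zswim9, 1.87 ± 0.211 TPM, and Rtl3, 3.33 ± 0.271 TPM. Without a filter 3 genes were called, without Oli-neu with D341 replicate 2 the count was 2, and with protein-coding genes alone Dhrs3 passed (adjusted p = 0.0407).

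**Figure D2:**
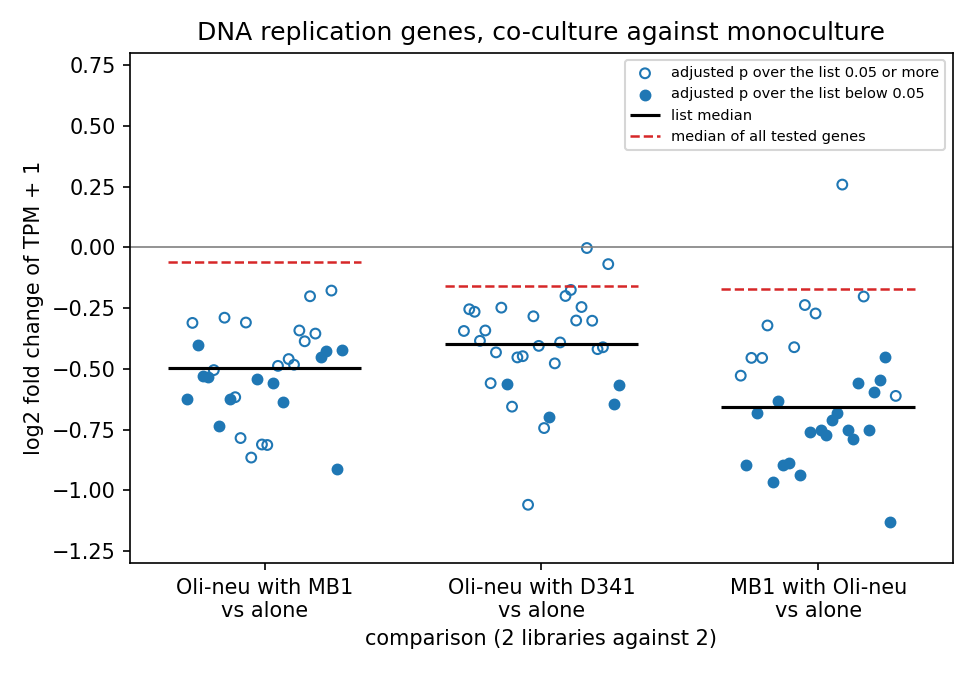
Log2 fold changes of TPM + 1 of the 30 DNA replication genes in 3 comparisons of co-culture with monoculture, where filled points passed when adjusted over the list alone, black lines are list medians and red dashed lines are medians of all genes tested. List medians were -0.50 and -0.40 in Oli-neu and -0.66 in MB1, each below the median of all genes.

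The responses of Oli-neu to its 2 partners were compared directly, as Oli-neu with D341 against Oli-neu with MB1. ERK targets were lower with D341 in 22 of 24 members, with a median of -0.26 against -0.09 for all genes tested (camera adjusted p = 1.16e-05, adjusted p = 0.285 with an estimated correlation), -0.28 and -0.26 within the numbers. The feedback inhibitors Spry4, at 8.50 ± 0.391 TPM with D341 and 12.5 ± 0.288 TPM with MB1, and Dusp6, at 51.7 ± 1.92 and 74.6 ± 1.47 TPM, and the early response factor Egr1, at 38.8 ± 0.854 and 60.5 ± 5.73 TPM (SD, n = 2), were lower when adjusted over the list alone. BMP targets were higher with D341 by a median of 0.18 (camera adjusted p = 4.98e-05, adjusted p = 0.285 with an estimated correlation), 0.21 and 0.19 within the numbers, and Id1 was higher when adjusted over the list alone, at 52.6 ± 0.421 against 23.2 ± 3.21 TPM (SD, n = 2; log2 fold change 1.15, SE 0.13). Oligodendrocyte precursor markers were lower in 16 of 18 members, with a median of -0.31 (camera adjusted p = 0.000939, adjusted p = 0.288 with an estimated correlation), -0.30 and -0.25 within the numbers. Gpr17, at 3.97 and 4.03 TPM against 7.08 ± 0.484 TPM, and Pdgfra, at 7.77 ± 0.912 against 12.6 ± 0.997 TPM, were lower when adjusted over the list alone.

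Adhesion genes had a median of -0.27 (camera adjusted p = 0.00899, adjusted p = 0.902 with an estimated correlation), and Nfasc, on chromosome 1 from 132564690 to 132741797, was lower when adjusted over the list alone, at 0.658 ± 0.166 TPM with D341 and 8.50 ± 3.47 TPM with MB1 (SD, n = 2). Heat shock genes had a median of 0.07 (0.000939, adjusted p = 0.294 with an estimated correlation), and Hspa1a, Hspa1b and Hsph1 were higher with D341 when adjusted over the list alone. Myelin genes were lower in 13 of 13 members, with a median of -0.18 (camera adjusted p = 0.0270, adjusted p = 0.327 with an estimated correlation). DNA replication (median 0.09, camera adjusted p = 9.73e-06) and interferon response genes (0.07, 0.0343) also had an adjusted p = 0.327 with an estimated correlation. The median was 0.05 for ribosomal protein genes (0.000939, adjusted p = 0.806 with an estimated correlation) and 0.06 for mitosis genes (0.00403, adjusted p = 0.915 with an estimated correlation). Within numbers 1 and 2 the medians were -0.34 and -0.22 for adhesion, -0.04 and 0.12 for heat shock, -0.24 and -0.23 for myelin, 0.09 and 0.10 for DNA replication, 0.03 and -0.04 for interferon, 0.11 and -0.00 for ribosomal proteins and -0.16 and 0.21 for mitosis. Extracellular vesicle genes had a median of -0.11 (adjusted p = 0.639) with 0 members passing when adjusted over the list alone.

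Without Oli-neu with MB1 replicate 2, 7 of the 10 lists did not pass: ERK and ribosomal (adjusted p = 0.0539 each), precursor and interferon (0.0625 each), heat shock (0.101), myelin (0.123) and mitosis, whose median turned to -0.17 (0.232). Without its replicate 1 myelin (0.105), interferon and adhesion (0.266 each) did not pass. Myelin (0.152), ribosomal (0.161) and interferon (0.172) were lost without Oli-neu with D341 replicate 1. Without its replicate 2 myelin and mitosis (0.0812 each), interferon and adhesion (0.169 each) were lost and 3 genes were called. Median-ratio scaling ended myelin (median -0.09, adjusted p = 0.0604) and interferon (0.17, 0.0892). Other medians with it were 0.17 for mitosis, 0.20 for DNA replication, 0.18 for heat shock, 0.16 for ribosomal, -0.21 for precursor and -0.17 for adhesion genes. With each of the 4 libraries left out in turn the medians ranged from 0.02 to 0.15 for DNA replication, -0.17 to 0.24 for mitosis, -0.05 to 0.15 for ribosomal, -0.10 to 0.21 for heat shock and -0.04 to 0.08 for interferon genes. The adhesion median was -0.14 and -0.44 without Oli-neu with MB1 replicates 1 and 2. Limma called 0 genes in this comparison over all libraries, with 630 at an unadjusted p under 0.05, close to the 614 expected if no gene differed. Of the 630, 97 were higher and 533 lower, and with median-ratio scaling the counts were 236 and 236. Among the genes with the smallest p, which did not pass, the transcriptional repressor Bcl6 was at 6.17 ± 0.0704 TPM with D341 and 11.7 ± 1.81 TPM with MB1 (SD, n = 2), Arhgap21 at 16.4 ± 0.0556 and 32.9 ± 2.77 TPM, Apbb2 at 2.91 ± 0.258 and 6.06 ± 0.301 TPM, Zfp365 at 2.71 ± 0.0486 and 6.25 ± 0.581 TPM, Zfp991 at 28.8 ± 1.03 and 15.2 ± 2.09 TPM and Zfp865 at 9.13 ± 0.369 and 4.43 ± 0.0116 TPM. Without a filter 6 genes were called and without a trend 1, and with protein-coding genes alone Gm10985 passed (adjusted p = 0.00822), at 0 and 0 TPM with D341 and 6.38 and 5.27 TPM with MB1.

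The 2 Oli-neu responses, each against Oli-neu alone, had 0 called genes in common, since limma called 0 in either. Across 12280 genes their log2 fold changes correlated with r = 0.622 and a Spearman rho of 0.592, where genes are not independent replicates. Simulated unchanged groups sharing the same monoculture libraries gave a mean r of 0.495, a covariance of 0.0654 against 0.0712 measured, and the same sign for 66.6% of genes against 73.3% measured. At an unadjusted p under 0.05, 361 genes were lower with both partners, against a mean of 77.3 and at most 105 in 100 such simulations and 69.1 from independent lists. With both partners 70 were higher, against a mean of 79.1 and at most 103 in the simulations and 2.84 from independent lists. These simulations took the libraries as independent, while the Oli-neu libraries separated by number. Simulations that kept the number gave a lower covariance and lower counts, so the values here do not show that the overlap is that of unchanged groups. The independent lists leave out the shared monoculture libraries, so part of any excess over them may come from those. The r was 0.825 without Oli-neu alone replicate 2 and 0.423 without Oli-neu with MB1 replicate 2. Leaving out a library also changes the r that unchanged groups would give, which was not simulated, so these values are not set against 0.495.

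MB1 cells beside Oli-neu were compared with MB1 cells alone, for the reverse effect on the tumour line. Inflammatory genes and targets of NF-kB were higher in co-culture in 13 of 17 members, with a median of 0.49 against -0.17 for all genes tested (camera adjusted p = 8.88e-11, adjusted p = 0.254 with an estimated correlation), 0.49 and 0.57 within the numbers and 0.17 without MB1 with Oli-neu replicate 2. Adjusted over the list alone 9 members rose and 1 fell. The monocyte chemokine Ccl2, on chromosome 11 from 82035571 to 82037453, rose from 0.528 ± 0.117 to 9.39 ± 0.395 TPM (SD, n = 2; log2 fold change 2.77, SE 0.16), and the neutrophil chemokine Cxcl1 rose from 0 and 0.153 TPM to 3.87 and 3.60 TPM. Nfkbia, the inhibitor that NF-kB induces, rose from 28.7 ± 4.71 to 55.9 ± 4.04 TPM and the alarmin Il33 from 39.7 ± 5.43 to 66.0 ± 6.45 TPM. Ccl7, Bcl3, Csf1 and Vcam1 also rose, lipocalin 2, Lcn2, was listed at 0 in both monoculture libraries and at 1.24 and 1.29 TPM in co-culture, and the superoxide dismutase Sod2 fell from 94.9 ± 8.81 to 67.4 ± 4.14 TPM.

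**Figure D3:**
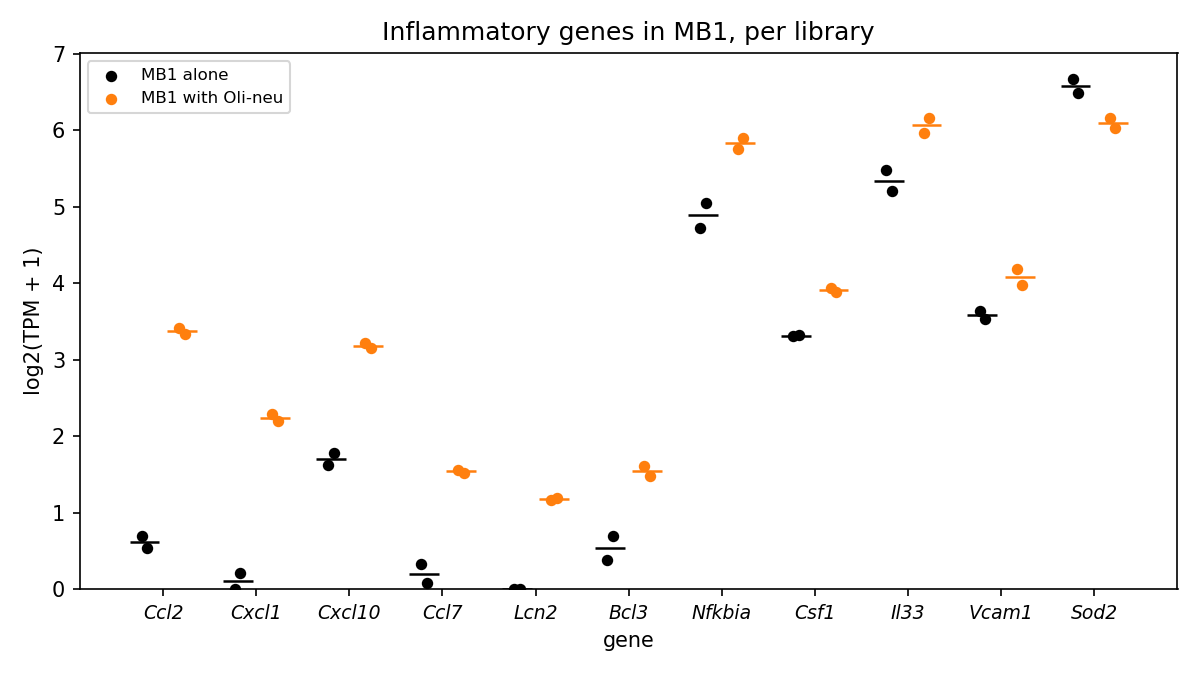
Expression of 11 inflammatory genes in each MB1 library, as log2(TPM + 1), alone and with Oli-neu, where points are libraries and bars are means of 2. Of the genes drawn, 10 were higher in co-culture and Sod2 was lower. They are the NF-kB list members that passed when adjusted over that list alone, with Cxcl10 of the interferon list. Their directions thus do not give the share of the list that was higher.

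DNA replication genes of MB1 were lower beside Oli-neu in 29 of 30 members, with a median of -0.66 (camera adjusted p = 1.55e-08, adjusted p = 0.416 with an estimated correlation), -0.77 and -0.55 within the numbers. Adjusted over the list alone 20 fell and 0 rose, among them Tyms from 30.2 ± 2.76 to 13.2 ± 1.63 TPM (SD, n = 2; log2 fold change -1.13, SE 0.17), the histone chaperone subunit Chaf1b from 18.4 ± 0.712 to 8.93 ± 0.636 TPM and the sliding clamp Pcna from 232 ± 35.6 to 144 ± 2.40 TPM. Mitosis genes were lower in 30 of 30 members, with a median of -0.50 (7.06e-06, adjusted p = 0.450 with an estimated correlation). Targets of MYC were lower in 28 of 30, with a median of -0.51 (1.33e-05, adjusted p = 0.254 with an estimated correlation), and 5 fell when adjusted over the list alone, among them the nucleolar protein gene Nop56 from 174 ± 1.23 to 100 ± 5.14 TPM. Genes of cholesterol synthesis had a median of -0.47 (0.000173, adjusted p = 0.439 with an estimated correlation), and 7 fell when adjusted over the list alone, among them Dhcr7, of the last step, from 316 ± 44.8 to 168 ± 19.6 TPM. Within numbers 1 and 2 the medians were -0.63 and -0.28 for mitosis, -0.57 and -0.41 for MYC targets and -0.39 and -0.61 for cholesterol synthesis. The mitosis median was -0.32 without MB1 alone replicate 1. With median-ratio scaling the medians were -0.31 for mitosis, -0.33 for MYC targets and -0.29 for cholesterol synthesis.

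Markers of other cell types were also among the lists past the threshold in MB1. Astrocyte markers had a median of 0.30 (camera adjusted p = 2.60e-07, adjusted p = 0.254 with an estimated correlation), 0.44 and 0.38 within the numbers. Adjusted over the list alone 5 rose, Clu, Atp1b2, Slc1a2, Apoe and Gfap, and Fabp7 fell. Clusterin, Clu, rose from 8.02 ± 0.201 to 19.0 ± 1.60 TPM and the intermediate filament gene Gfap from 3.42 ± 1.06 to 7.76 ± 2.16 TPM (SD, n = 2). Of 18 listed markers of endothelial cells, pericytes and fibroblasts only 5 passed the filter of 1 TPM and were tested. These had a median of 0.56 (3.85e-05, adjusted p = 0.254 with an estimated correlation). Thy1, from 12.3 ± 2.32 to 30.6 ± 4.97 TPM, and Pecam1, from 1.21 ± 0.368 to 3.30 ± 0.911 TPM, rose when adjusted over the list alone. Interferon response genes had a median of 0.28 (1.33e-05, adjusted p = 0.254 with an estimated correlation), and the chemokine Cxcl10 rose when adjusted over the list alone, from 2.25 ± 0.254 to 8.09 ± 0.339 TPM. TGF-beta and matrix genes had a median of 0.20 (5.68e-05, adjusted p = 0.254 with an estimated correlation), and the protease inhibitor Timp1 rose from 6.04 ± 0.616 to 13.7 ± 1.42 TPM when adjusted over the list alone. Within numbers 1 and 2 the medians were 0.65 and 0.48 for endothelial and fibroblast markers, 0.21 and 0.28 for interferon and 0.45 and 0.18 for matrix genes. MB1 alone replicate 2 lay at -46.3 on the first principal component, against 2.54, 18.1 and 25.7 for the other MB1 libraries. Without it the medians were 0.56 for astrocyte and 0.40 for matrix genes. The median of endothelial and fibroblast markers was 0.34 without MB1 alone replicate 1, and that of matrix genes 0.09 without MB1 with Oli-neu replicate 1. With median-ratio scaling the medians were 0.48 for astrocyte and 0.34 for matrix genes. The endothelial and fibroblast median was 0.93 with a pseudocount of 0.1 TPM.

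Extracellular vesicle genes of MB1 had a median of 0.02, with 22 of 44 members higher (camera adjusted p = 0.00173, adjusted p = 0.416 with an estimated correlation), and 0.08 and -0.03 within the numbers. The membrane-binding annexin Anxa5 rose from 26.7 ± 1.54 to 55.7 ± 1.09 TPM and the tetraspanin Cd82 fell from 3.61 ± 0.368 to 0.983 ± 0.265 TPM (SD, n = 2) when adjusted over the list alone. Wnt pathway genes had a median of -0.36 (0.0305, adjusted p = 0.416 with an estimated correlation), and Apcdd1, Wnt7a and Wnt5a fell when adjusted over the list alone, Wnt7a from 43.5 ± 0.620 to 21.7 ± 1.56 TPM. Genes of hypoxia and glycolysis had a median of -0.31 (0.0370, adjusted p = 0.641 with an estimated correlation), and Hk2, Ankrd37, Egln3, Pdk1 and Bnip3 fell when adjusted over the list alone, hexokinase 2, Hk2, from 30.5 ± 0.831 to 12.0 ± 1.77 TPM. Notch genes had a median of -0.29 (0.0441, adjusted p = 0.439 with an estimated correlation). The small heat shock protein gene Cryab rose from 72.2 ± 8.63 to 157 ± 6.84 TPM when adjusted over the heat shock list alone, whose median was 0.01 (0.0358, adjusted p = 0.505 with an estimated correlation). Within numbers 1 and 2 the medians were -0.51 and -0.35 for Wnt, -0.19 and -0.53 for hypoxia, -0.51 and -0.36 for Notch and -0.17 and 0.08 for heat shock.

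Another 5 lists passed the threshold in MB1. Ribosomal protein genes had a median of 0.19 (camera adjusted p = 7.87e-09, adjusted p = 0.254 with an estimated correlation). The nuclear genes of oxidative phosphorylation (median 0.09, camera adjusted p = 2.89e-05), lysosome genes (0.18, 6.02e-05) and p53 targets (-0.03, 0.00463) had an adjusted p = 0.439 with an estimated correlation. The mean of the p53 targets was 0.10 and their test gave a higher direction. Mitochondrially encoded genes had a median of 0.45 (0.00348, adjusted p = 0.507 with an estimated correlation), -0.14 within number 1 and 0.72 within number 2, and -0.26 and 0.76 without MB1 alone replicates 2 and 1. Within numbers 1 and 2 the other medians were 0.18 and 0.16 for ribosomal proteins, 0.23 and -0.05 for oxidative phosphorylation, 0.10 and 0.06 for lysosomes and 0.08 and -0.07 for p53 targets. Without MB1 alone replicate 1 the adjusted p was 0.0824 for vesicle genes, 0.0911 for heat shock, 0.151 for p53 and for Notch and 0.0657 for Wnt. It was 0.177 for Notch without MB1 alone replicate 2, 0.0966 for p53 without MB1 with Oli-neu replicate 1, and 0.123 for heat shock, 0.163 for Notch and 0.0622 for Wnt without MB1 with Oli-neu replicate 2, while median-ratio scaling gave 0.0581 for Wnt. With protein-coding genes alone the Wnt list did not pass (median -0.23, adjusted p = 0.127), and the medians were 0.09 for vesicle, 0.04 for heat shock and -0.01 for p53 genes. With median-ratio scaling the median of all genes tested was -0.00. List medians were then 0.25 for vesicle, 0.18 for heat shock, 0.14 for p53, 0.28 for oxidative phosphorylation, 0.37 for lysosome and 0.38 for ribosomal genes. They were -0.18 for Wnt, -0.12 for hypoxia and -0.11 for Notch genes. The hypoxia list was at 0.555 without MB1 alone replicate 2, and 0.112 and 0.0622 without MB1 with Oli-neu replicates 1 and 2. Its median was -0.49 and -0.18 without MB1 alone replicates 1 and 2. With each of the 4 libraries left out in turn the medians ranged from -0.02 to 0.11 for vesicle, -0.15 to 0.03 for heat shock, -0.04 to 0.03 for p53, 0.05 to 0.15 for oxidative phosphorylation and 0.04 to 0.18 for lysosome genes.

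Over all genes limma called 0 genes in MB1, with 1944 at an unadjusted p under 0.05, against 620 expected if no gene differed. Of the 1944, 375 were higher and 1569 lower, and with median-ratio scaling the counts were 838 and 579. Among the genes with the smallest p, which did not pass, Agtrap, which binds the angiotensin receptor, was at 20.8 ± 2.29 TPM alone and 3.92 ± 0.00902 TPM with Oli-neu (SD, n = 2), and the histone deacetylase gene Hdac11 at 10.1 ± 1.31 and 1.45 ± 0.0607 TPM. The retinaldehyde dehydrogenase Aldh1a1 was at 8.35 ± 0.173 and 21.3 ± 0.636 TPM, Rab26 at 8.69 ± 1.11 and 26.6 ± 2.69 TPM, and the lamin B receptor, Lbr, at 28.5 ± 1.65 and 10.7 ± 0.899 TPM. Ccdc120, Prr14l and Tedc1 were lower by a log2 fold change of -2.25, -1.96 and -1.35. With protein-coding genes alone Agtrap (adjusted p = 0.0361), Hdac11 (0.0361), Cxcl1 (0.0361), Ccl2 (0.0217) and Pde6h (0.0470) passed. Called counts were 9 with robust=TRUE and, with 1 library left out, 112 without MB1 alone replicate 1, 2 without MB1 with Oli-neu replicate 1 and 1 without either of the other libraries.

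**Figure D4:**
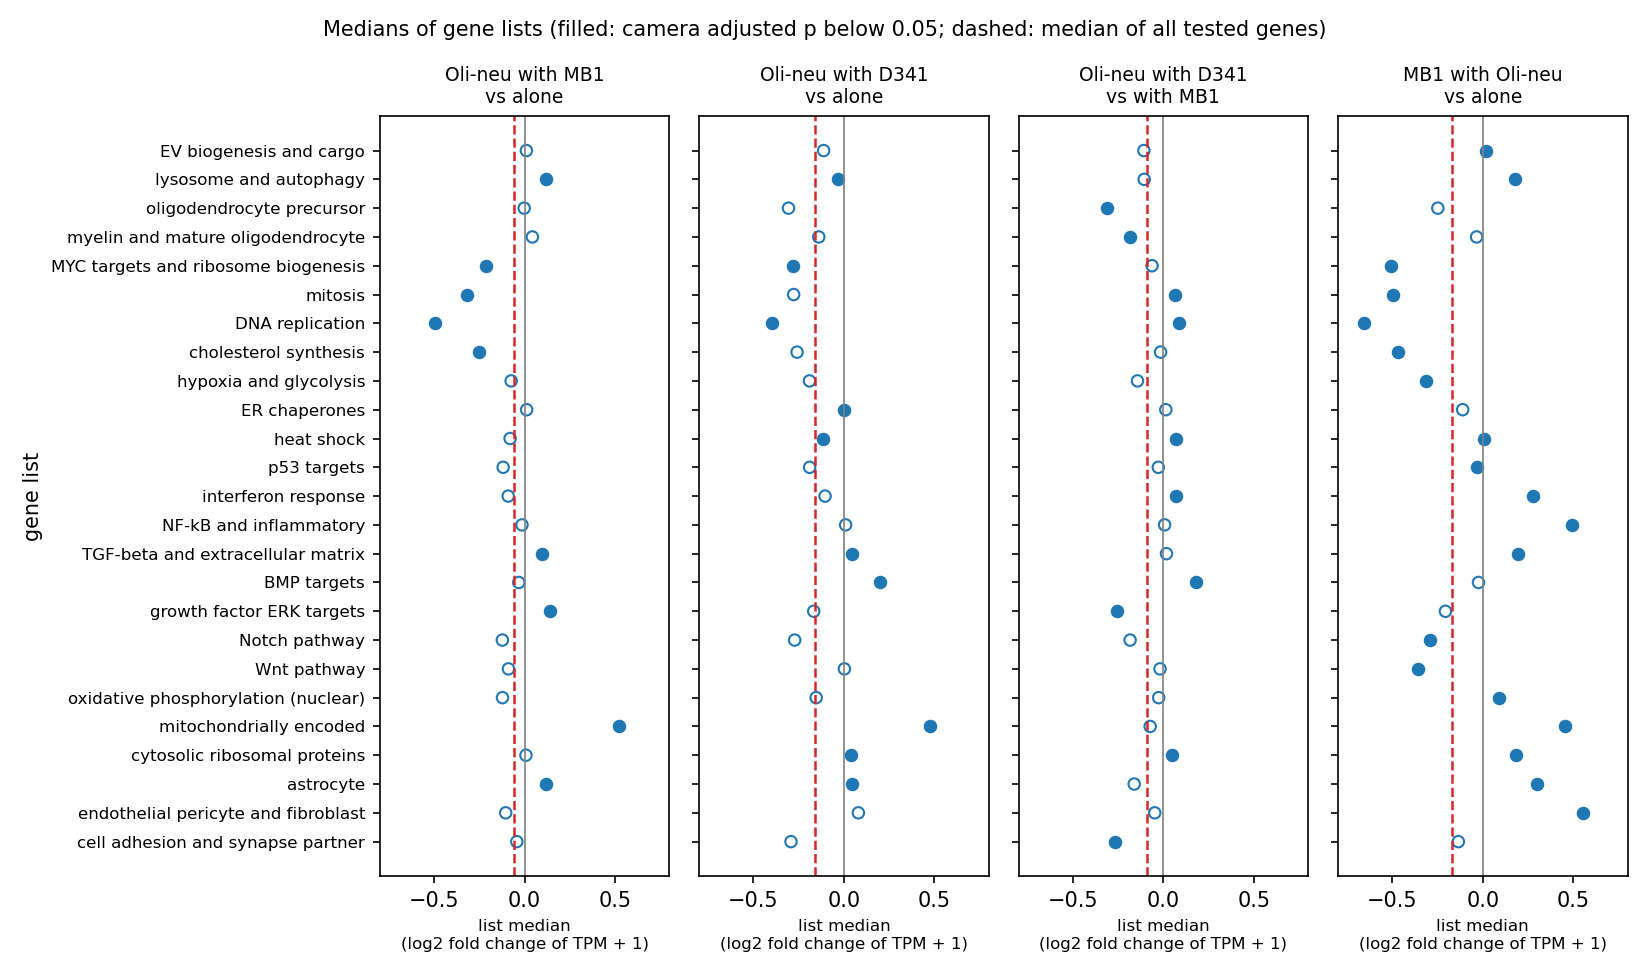
Median log2 fold changes of 25 gene lists in the 4 mouse comparisons, where filled points had a camera adjusted p under 0.05 and red dashed lines are medians of all genes tested. DNA replication lay at -0.50, -0.40 and -0.66 in co-culture against monoculture, and 0 lists passed with an estimated correlation in any of the 4.

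D341 cells beside Oli-neu were compared with D341 cells alone. Limma called 78 genes, 44 higher and 34 lower in co-culture, of which 75 had an absolute log2 fold change of at least 1. More were lower than higher with a pseudocount of 5 TPM (57 higher and 90 lower), a filter of 5 TPM (53 and 84), no trend (49 and 85) and robust=TRUE (94 and 320). At an unadjusted p under 0.05 there were 4250, against 620 expected if no gene differed. Of the 4250, 431 were higher and 3819 lower, and the median of all genes tested was -0.31. The gene ENSG00000219928 was listed at 0 in both monoculture libraries and at 284 and 181 TPM in co-culture (adjusted p = 0.00635), and ENSG00000133136 at 0 in both and at 10.5 and 28.6 TPM (adjusted p = 0.0464, and 0.173 and 0.208 without D341 alone replicates 1 and 2). In the other direction, ENSG00000227689 was at 25.1 and 42.0 TPM alone (adjusted p = 0.0196) and ENSG00000241069 at 39.0 and 16.5 TPM (adjusted p = 0.0353), and both were listed at 0 in co-culture. Of the 44 higher genes 12 were at 0 in both monoculture libraries, and of the 34 lower genes 2 were at 0 in both co-culture libraries. The classes of the human genes are unknown here, so pseudogenes among the called genes could not be told apart. In the mouse lines pseudogenes were 66.7% to 87.2% of the genes with an absolute log2 fold change of at least 2. Carry-over of Oli-neu RNA into the D341 libraries was not tested. With median-ratio scaling 261 genes were called, 164 higher and 97 lower, and the genes at an unadjusted p under 0.05 were 1765 higher and 1768 lower. The count was 0 without a filter, 1 without either D341 alone library, 524 without D341 with Oli-neu replicate 1 (112 higher and 412 lower) and 2484 without replicate 2 (158 and 2326).

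Transcripts of the partner line were followed in the mouse co-cultures, as a measure of RNA or cells passing between compartments. In Oli-neu with MB1, 18 genes that MB1 expressed and Oli-neu alone did not were at 0.00118% and 1.03% of their MB1 level in the 2 libraries, and in Oli-neu with D341, where MB1 was absent, at 0.0687% and 0.00707%. Most of the higher value came from the pseudogene Smt3h2-ps4. In MB1 with Oli-neu, 6 genes of Oli-neu were at 0.0287% and 0.137% of their Oli-neu level. Most of these genes are annotated as pseudogenes. Gm10240, at 3224 TPM in Oli-neu alone and 0 TPM in MB1 with Oli-neu, held most of their summed Oli-neu level. Most of the transcripts found came from Gm49330, at a mean of 2.49 TPM in MB1 with Oli-neu. The shares thus rest largely on single pseudogenes.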

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

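The test of scaling for the DNA replication genes and the tests of microglia and of retinoid signalling were chosen after the results they bear on were seen. The other tests are recorded as written before their outcome. They too were set for patterns already seen, such as the rise of Dhrs3, so they were not planned before the data were examined. The values that would speak against higher retinoid signalling were set again after the p of its test was known, to a p under 0.05 in the lower direction with either partner. Before that, a p above 0.05 or a lower direction, with a median under 0.1, counted against it.

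DNA replication genes were lower in co-culture than alone in Oli-neu with either partner, where mitochondrially encoded genes were higher in 13 of 13 (medians 0.52 and 0.47). They were also lower in MB1, where astrocyte (0.30) and endothelial markers (0.56) were higher. With each MB1 library left out in turn the DNA replication median ranged from -0.74 to -0.57. The value of -0.74 was without MB1 alone replicate 2, which lay apart on the first principal component (-46.3). MB1 alone replicate 1 lay apart on the second (37.6 against -10.1, -18.7 and -8.75). The tables argue against a shift of all genes by TPM scaling, since with median-ratio scaling the highest of the 3 list medians was -0.24. That scaling mainly removes the common shift, so the value restates the gap between the list and all genes tested. The tables also argue against the expression level or transcript length of these genes, since 0% of 10000 random lists matched for both had a median as low in any of the 3 comparisons (lowest random median -0.22, -0.33 and -0.44 against -0.50, -0.40 and -0.66). An effect of any second cell population in the medium, whatever its kind, cannot be told apart from an effect of the partner line, since 0 groups had a partner of the same line. Slower proliferation may be a candidate explanation and was not tested, since no count of cells was used, and mitosis genes had medians of -0.32 with MB1 (-0.05 and an adjusted p of 0.287 without Oli-neu with MB1 replicate 2), -0.28 with D341 (adjusted p = 0.0795, which did not pass) and -0.50 in MB1. The Oli-neu comparisons share their monoculture libraries, so they are not independent of each other. With an estimated correlation the DNA replication list passed in 0 of the 3 comparisons, so the pattern stays a hypothesis.

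Inflammatory genes and targets of NF-kB were higher in MB1 with Oli-neu than alone, as were astrocyte markers (median 0.30, 12 of 15 higher). Markers of endothelial cells, pericytes and fibroblasts were also higher (0.56, 5 of 5 tested, of 18 listed). With each MB1 library left out in turn the NF-kB median ranged from 0.17 to 0.57. The value of 0.57 was without MB1 alone replicate 2, which lay apart on the first principal component (-46.3 against 2.54, 18.1 and 25.7). MB1 alone replicate 1 lay apart on the second (37.6 against -10.1, -18.7 and -8.75). The tables argue against Oli-neu RNA or cells carried over, since the measured share of Oli-neu transcripts would give a median of 0.00263% of the rise of the members that rose. That share rests largely on pseudogenes and is uncertain. Of the members that rose, only Nfkbia had a level in Oli-neu with MB1 (29.8 TPM) above its rise in MB1 (27.2 TPM). The others, such as Ccl2 (0.0205 against 8.86 TPM), had Oli-neu levels below their rise. The tables also argue against microglia or macrophages in the co-culture, whose 16 markers had a median of 0.00112 TPM there. Of these markers 2 reached 1 TPM, among them Cd68 at 5.83 TPM alone and 16.6 TPM in co-culture, whose values had been seen before the test was chosen. Cells of those other types, and a response of MB1 cells to Oli-neu or to any second population, may account for the pattern and were not tested.

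Dhrs3 was at higher levels in Oli-neu with either partner, against the same Oli-neu alone libraries, so these are not independent repeats. The tables argue against MB1 RNA or cells carried over, since the measured share of MB1 transcripts would give 0.0822% of the rise, with Dhrs3 at 0.692 TPM in MB1 with Oli-neu. Higher retinoid signalling stays open only under the rule as reset. The retinoid list with D341 had an unadjusted camera p of 0.0726 in the higher direction (0.201 with an estimated correlation). With D341, 3 of 11 members were above 0, with a median of -0.12 against -0.16 for all genes. Under the earlier rule this result with D341 would have counted against higher retinoid signalling. With MB1 9 of 11 were higher, with a median of 0.06 and a p of 0.00603 (0.0877 with an estimated correlation), and without Mgp, a listed gene that had already been seen to be high, the p was 0.0454 with MB1 and 0.427 with D341 (0.128 and 0.468 with an estimated correlation). Carry-over from D341 was not tested.

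The direct comparison of Oli-neu with D341 against Oli-neu with MB1 tests the difference between the responses, and 10 lists passed in it. The medians were 0.0893 for DNA replication, -0.26 for ERK targets, 0.18 for BMP targets, 0.0478 for ribosomal proteins, 0.0700 for heat shock, -0.31 for oligodendrocyte precursor markers, 0.0635 for mitosis, -0.27 for adhesion, -0.18 for myelin and 0.0694 for interferon response genes. With an estimated correlation 0 of these passed.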

How the results depend on the processing

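The test of protein-coding genes alone and the simulated counts of genes at an unadjusted p under 0.05 were chosen after seeing the data, and the other alternatives here before. With an estimated correlation 0 lists passed in each of the 4 mouse comparisons, with the smallest adjusted p at 0.180 for Oli-neu with MB1 against alone, 0.536 for Oli-neu with D341 against alone, 0.285 for Oli-neu with D341 against with MB1 and 0.254 for MB1. With fry, which tests against no change and not against other genes, 3, 5, 3 and 0 lists passed in the same order. The lysosome list of Oli-neu with D341, with a median of -0.0331, took the lower direction with fry. In Oli-neu with MB1 against alone limma called 3 genes with a pseudocount of 0.1 TPM, 1 with no filter, 2 with median-ratio scaling, 1 without a trend and 2 among protein-coding genes only. In Oli-neu with D341 against alone it called 3 genes with no filter and 1 among protein-coding genes only, and in Oli-neu with D341 against with MB1 6 with no filter, 1 without a trend and 1 among protein-coding genes only. In MB1 it called 9 genes with robust=TRUE and 5 among protein-coding genes only. In D341, against 78, it called 147 genes with a pseudocount of 5 TPM, 0 with no filter, 137 with a filter of 5 TPM, 261 with median-ratio scaling, 134 without a trend, 414 with robust=TRUE and 3475 with the replicate block (326 higher and 3149 lower), of which 76, 66, 74, 72, 78 and 78 were among the 78 for all but no filter.

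With the replicate number as a term (replicate block) the other 4 comparisons had 0 genes called, the astrocyte list of Oli-neu with D341 had an adjusted p of 0.0909 and the hypoxia list of MB1 one of 0.0967. The labels do not say what the numbers mark. The deviations of equally numbered libraries from their group means correlated across genes with r of 0.618, 0.593 and 0.614 between the Oli-neu groups, -0.115 in MB1 and 0.210 in D341, where genes are not independent replicates. With the spread taken from that fit, the simulations of unchanged Oli-neu groups gave a mean covariance of 0.0225 and a mean r of 0.499, against a covariance of 0.0654 without the term and 0.0712 measured. With the number kept in the simulated libraries, a mean of 15.2 genes were lower and 15.2 higher with both partners at an unadjusted p under 0.05, and at most 23 and 28, against 361 and 70 measured.

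With 1 library left out, the number of lists past the threshold ranged from 5 (without Oli-neu alone replicate 2) to 12 in Oli-neu with MB1, from 5 (without Oli-neu alone replicate 2) to 11 in Oli-neu with D341 and from 3 (without Oli-neu with MB1 replicate 2) to 9 between the partners. Genes called ranged from 0 to 2 in Oli-neu with D341 against alone and from 0 to 3 between the partners, the higher counts without Oli-neu with D341 replicate 2, from 1 to 112 in MB1 (112 without MB1 alone replicate 1) and from 1 to 2484 in D341 (1 without either D341 alone library, 2484 without D341 with Oli-neu replicate 2). The correlation of the Oli-neu responses ranged from 0.423 to 0.825, where the value for unchanged groups also changes with the library left out and was not simulated. Between the partners the mitosis median ranged from -0.17 to 0.24, Prc1 from -0.54 to 0.0543 and Rps7 from -0.0160 to 0.47. In MB1 the median of mitochondrially encoded genes ranged from -0.26 to 0.76, mt-Atp6 from -0.21 to 1.90 and mt-Nd4 from -0.0677 to 2.20, negative without MB1 alone replicate 2. For the changed results the cause was not tested. Of the list results with 1 library left out, 28 of 36, 28 of 40, 23 of 40 and 62 of 76 kept the direction given by camera and their side of the threshold, and some of their medians near 0 changed sign. For D341 the list tests, the rescaling without mitochondrially encoded genes and the test of protein-coding genes were not run, since identifiers were not paired with names here. Depth is unknown, so a value of 0 TPM is not shown to be absence.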

Other observations

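The genes here were chosen after their values were seen, from lists that did not pass as a whole. In MB1 with Oli-neu the adhesion receptor Cd44 rose from 18.6 ± 0.630 to 31.7 ± 0.902 TPM (SD, n = 2) and the transcription factor Sox3 fell from 44.3 ± 4.22 TPM to 25.8 and 18.1 TPM in the 2 libraries, each adjusted over the list of neural stem and radial glia genes alone. The stress response genes Trib3, from 4.16 ± 1.25 to 1.17 ± 0.126 TPM, and Chac1, from 4.54 ± 0.867 to 1.68 ± 0.202 TPM, fell when adjusted over their list alone. The photoreceptor phosphodiesterase subunit Pde6h rose in the same way, from 0.0199 ± 0.0140 to 2.26 ± 0.215 TPM.

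In Oli-neu with D341, Gas1, a co-receptor of hedgehog signalling, fell from 15.5 ± 1.07 to 9.28 ± 0.518 TPM, and the myelin genes Cnp from 24.8 TPM to 17.1 ± 1.42 TPM and Fa2h from 3.83 ± 0.314 to 2.12 ± 0.378 TPM (SD, n = 2), each adjusted over its list alone. The matrix gene Mgp was at 855 ± 286 TPM in Oli-neu alone, 2091 ± 430 TPM with MB1 and 3623 ± 790 TPM with D341 and did not pass over all genes (adjusted p = 0.715 and 0.320).

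Among genes with an absolute log2 fold change of at least 2, pseudogenes were 39 of 46 in Oli-neu with MB1, 41 of 47 in Oli-neu with D341 and 56 of 84 in MB1 with Oli-neu, against 9.92% of the genes tested in Oli-neu and 6.98% in MB1. Lists past the threshold in opposite directions in Oli-neu and MB1 numbered 0.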
